A study of Daphnia magna with 27 samples.

How the data were processed

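RNA of whole adult Daphnia magna, clone K6, was measured on 27 arrays with 2 dye channels, 3 per group in 9 groups, each sample made from 10 animals. Per the labels, one channel held the sample and the other a common reference pool of animals of mixed ages, and the dyes were exchanged between arrays. The labels do not say whether the 3 replicates of a group came from separate cultures, so every p below measures a difference against the spread between arrays. In the main fit that spread was pooled over all 9 groups, 1 value per probe, although arrays differed in spread. The median SD across probes was 0.97 on the 6 CtrlF2 and Zn(+)F2 arrays and 0.45 on the other 21. A p can thus be too small where CtrlF2 or Zn(+)F2 is compared and too large elsewhere.

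The table of values was deposited as log2 ratios, 1 per probe and array, and the labels name limma without a version. Background correction, normalization and filters are not stated. The log2 unit and the direction, sample over reference, were not in the labels and were taken from the deposited tables. A regression of the authors' log2 changes on the arrays gave R squared of 0.946 for ZnF0 against CtrlF0, 0.922 for CtrlF1 against CtrlF0, 0.867 for CtrlF1 against CtrlF2 and 0.695 for CtrlF2 against CtrlF0, with the signs of that direction. In CtrlF2 and Zn(+)F2 the array medians changed sign with the dye, from -0.33 and -0.40 with the sample in Cy3 to 0.35 and 0.32 in Cy5. No deposited table covers Zn(+)F1, Zn(-)F1, Zn(+)F2, Zn(+/-)F2 or Zn(-/-)F2. Within groups of both dyes, Cy3 and Cy5 arrays correlated at r = 0.344 and 0.434 in Zn(+/-)F2, 0.413 and 0.757 in Zn(-/-)F2, 0.273 and 0.274 in CtrlF2, and 0.030 and -0.127 in Zn(+)F2, so that the first 3 of these ran the same way in both dyes. Zn(+)F1 and Zn(-)F1 held Cy3 alone, and their direction, like that of the Cy3 array of Zn(+)F2, rests on the same rule. The other direction of all Cy3 arrays was tried as an alternative. The authors also deposited 4 limma tables, per the file headers with the log2 change and the mean log2 expression, the moderated t-statistic and the log odds (both a score), and the raw and adjusted p-value (p_value). They were set beside the values computed here and entered no test.

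The table held 2261 probes. A name stood in the annotation column for 27 and in the probe identifier for 13, which gave 40 named probes; another 44 were marked unknown and 2177 had no entry. The reference list of symbols could not be matched to the probes, so no position in a genome is given. An array measures no counts, and its precision is limited by the number of arrays. Arrays held values for 2066 to 2254 probes, except Zn(+)F1 replicate 2 with 886. The columns of CtrlF0 replicates 1 and 3 were equal within 0.001 at 2066 of 2066 probes, the largest difference being 0.00026, while any other pair shared at most 0.540% of its values. These columns were averaged and counted as 1 sample, which left 26 samples in the fit and n = 2 for CtrlF0.

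Each comparison was a contrast of one fit in limma 3.58.1 (R 4.3.3; lmFit and eBayes), with a coefficient for each group and 1 for the dye of the sample, on the values as deposited. The dye coefficient could be estimated from the 4 F2 groups alone, since only they held both dyes. Probes with at least 2 values in each compared group were tested, and a Benjamini-Hochberg adjusted p under 0.05 was the threshold. There were 8 comparisons of exposure, 3 of controls between generations and 2 tests of a difference between the effects of zinc in 2 generations. Group values are given after removal of the dye coefficient, as mean ± SD, and log2 changes with their SE. Means and SDs in the text are in log2 units of the ratio to the reference pool.

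Named genes were taken by a rule. It took, per comparison of exposure, the 12 largest rises and 12 largest falls among named probes past the threshold whose arrays did not overlap between the groups, 1 probe per name, all of them if fewer passed, and then the 6 of smallest p that did not pass. For controls it took the 5 largest in each direction. Vitellogenin, hemoglobin, ferritin and metallothionein probes were included where present. Of the probes without a name, at most 2 that rose and 2 that fell are given per comparison. Of 19 gene lists fixed by name patterns, those on chaperones, digestive proteases, digestive carbohydrases, cuticle and moulting, translation factors, immunity, and neural and visual markers matched no probe. The lists on ribosomal proteins, cell cycle, and algal and bacterial RNA matched 2 probes each, and those on oxidative phosphorylation, glycolysis and citrate cycle, lipid handling, muscle and cytoskeleton, and ubiquitin and proteasome matched 1 each, fewer than the 3 needed for a test. The 4 lists tested were yolk and egg (3 probes), globins and iron (4), metal and redox defence (6) and chromatin and methylation (3). A list of the 5 cyplasin s probes was added after the data were seen. Lists were tested with cameraPR at an inter-gene correlation of 0.01, in 26 tests, and again with the correlation estimated from the residuals, and with fry on the members measured on every array but Zn(+)F1 replicate 2 (for yolk and egg 2 probes, Rep_ASP1 F6 and H2, under the minimum of 3). The comparisons, the tests, the 19 lists, the naming rule and the alternatives called planned were set before the data were examined.

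The whole procedure was tested on simulated data in which 100 probes per size were changed. At a log2 change of 1 the share recovered ran from 41% in Zn(+)F1 against CtrlF1 to 72% in Zn(+/-)F2 against CtrlF2 over the comparisons of exposure, and at a log2 change of 2 from 84% to 94%. For the differences between generations it was 21% and 31% at a log2 change of 1. Alternatives were no dye coefficient, only the arrays of the compared groups, arrays median-centred and scaled, only probes measured on all arrays, array weights, robust eBayes, a replicate block, the sign turned for arrays with the sample in Cy3, and each replicate left out in turn. The alternative with the arrays of the compared groups alone also had no dye coefficient. Added after the data were seen were median-centring alone, CtrlF0 replicates 1 and 3 as 2 samples, values beyond 5 set to missing, the 6 arrays that were not centred left out, and Zn(+)F1 replicate 2 left out. Correlations of effects across probes were set beside 50 simulated draws with unchanged groups in the same design, in which all arrays had 1 spread per probe. Overlaps of calls were set beside lists of the observed sizes taken by smallest p in those draws, a step added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.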

Results

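Gene expression was measured in whole Daphnia magna, a water flea that reproduces clonally, over 3 generations of zinc exposure and of return to clean medium. A control line was sampled as CtrlF0 at 20 days of age, CtrlF1 at 22 days and CtrlF2 at 20 days. Animals reared in zinc at 388 µg/L formed ZnF0, sampled at 23 days. Their offspring stayed in zinc as Zn(+)F1 or went back to control medium as Zn(-)F1, both sampled at 21 days. Offspring of Zn(+)F1 stayed in zinc as Zn(+)F2 (21 days) or went back as Zn(+/-)F2 (22 days), and offspring of Zn(-)F1 remained in control medium as Zn(-/-)F2 (22 days). Every comparison with the control of the same generation thus also differed in age, and exposure and age cannot be told apart there. Of the comparisons of exposure, only Zn(+)F1 against Zn(-)F1 was matched in age. Each of the 9 groups had 3 arrays, but CtrlF0 counted as n = 2 because 2 of its columns held equal values. Zn(+)F1 replicate 2 had values for 886 probes only, against 2066 to 2254 on the other arrays, and correlated with other arrays at r from -0.099 to 0.074. It gave no value at the called named probes, where n is therefore 2 for Zn(+)F1. Of the 2261 probes 40 carried a name, so that most changes below belong to probes known only by their identifier.

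The deposited values of CtrlF2 and Zn(+)F2 differed from those of the other 7 groups. The medians of these 6 arrays lay 0.31 to 0.40 from 0 on the log2 scale, with a sign set by the dye of the sample, while those of the other 21 arrays lay within 0.072. They also held 100 values beyond 5, against 2 in the other arrays. These groups alone carried such offsets, and through the dye coefficient they shifted the comparisons of Zn(+)F1 and Zn(-)F1, so the calls of each comparison, over all probes and over named ones, are counted both on the values as deposited and after median-centring of every array.

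**Figure D1:**
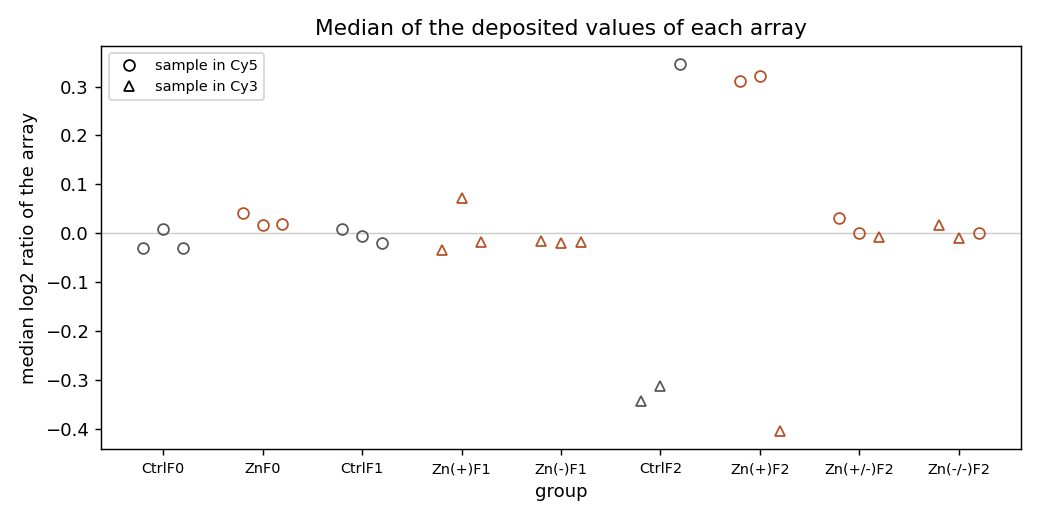
Median log2 ratio to the reference pool (vertical axis) of each array by group (horizontal axis); circles mark the sample in Cy5 and triangles the sample in Cy3, grey control groups and brown groups from exposed F0. The 3 CtrlF2 and 3 Zn(+)F2 arrays lie 0.31 to 0.40 from 0, the other 21 arrays within 0.072.

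The comparison of ZnF0 with CtrlF0 asked what direct exposure changed in the first generation, though the animals also differed in age, at 23 and 20 days. The cyplasin s probe Rep_ASP8 F6, named after cytotoxic glycoproteins of sea hares, fell by 0.68 on the log2 scale (SE 0.17, adjusted p = 0.032), from -0.12 ± 0.018 (SD, n = 2) in CtrlF0 to -0.80 ± 0.10 (SD, n = 3) in ZnF0. All 3 ZnF0 arrays lay below both CtrlF0 arrays, but the arrays of these groups did not overlap at 48.4% of all tested probes. The vitellogenin precursor probe Rep_ASP1 H2, for the main yolk protein, stood at 0.30 ± 0.066 in ZnF0 and -0.22 ± 0.14 in CtrlF0, a log2 change of 0.52 that did not pass (SE 0.24, adjusted p = 0.24). Other named probes also did not pass: rib 40S of the small ribosomal subunit gave 0.77, rib 16S Rep_ASP1 B5 0.59, cyplasin s Rep_ASP8 A7 0.45, nucleosome assembly -0.39 and cyclin b3, a regulator of mitosis, -0.29. For the iron store ferritin (ferritine_oud) the change was -0.13, and for metallothionein, the metal-binding protein probed as Mta_oud, 0.08. In all, 1 of 29 named probes passed, 1 when adjusted over the list alone and 1 after centring. Among 1993 probes, 111 passed, 28 higher and 83 lower in ZnF0; after centring 238 did, 61 higher and 177 lower. The probe Mol_ASP2 H4 rose by 2.47 (SE 0.34, adjusted p = 6.2e-04), Mol_ASP6 C1 by 1.84, and the lower ones were led by Mol_ASP6 A3 at -2.37 and Mol_ASP8 D4 at -2.35. The count was 9 without the averaged CtrlF0 array, 65 without CtrlF0 replicate 2, 16 without ZnF0 replicate 1, 17 without ZnF0 replicate 3, 37 with a replicate block, 29 without the dye coefficient and 393 without the 6 arrays that were not centred. The excess of lower calls did not hold there (199 higher and 194 lower) or with the arrays of the compared groups alone (158 higher and 72 lower). The call of cyplasin s ended without the dye coefficient (adjusted p = 0.13; 0.0011 to 0.13 over the alternatives), with the block (0.056), and without the averaged CtrlF0 array (0.28), CtrlF0 replicate 2 (0.087), ZnF0 replicate 1 (0.13) or ZnF0 replicate 3 (0.057); without CtrlF0 replicate 2, rib 40S at 1.39 (0.046) and rib 16S at 1.18 (0.041) passed.

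Zn(+)F1 against CtrlF1 asked what a second generation in zinc changed. All probes together were shifted upwards, with a median log2 change of 0.36. The called named probes and vitellogenin Rep_ASP1 G1 are also given relative to that median. Other changes include the shift, so that chromobox at 0.40 lies close to it. The cyplasin s probe Rep_ASP8 F6 rose by 1.06 (SE 0.20, adjusted p = 0.0030), from -0.71 ± 0.035 (SD, n = 3) to 0.34 ± 0.23 (SD, n = 2), which was 0.69 above the median of all probes. Both vitellogenin probes were higher in Zn(+)F1: Rep_ASP1 F6 by 0.94 (SE 0.28, adjusted p = 0.031), from -0.38 ± 0.11 to 0.56 ± 0.20, and the precursor Rep_ASP1 H2 by 0.91 (SE 0.29, adjusted p = 0.045), from -0.36 ± 0.29 to 0.54 ± 0.087. Relative to the median of all probes these were 0.58 and 0.54, and after centring neither passed (adjusted p = 0.089 and 0.13; 0.023 to 0.74 and 0.035 to 0.76 over the alternatives). The other vitellogenin probe, Rep_ASP1 G1, lay below that median, at -0.36 relative to it, and did not pass. The yolk and egg list thus had 2 of 3 members past the threshold and 2 when adjusted over the list alone, with a median of 0.91 but a list test that did not pass (adjusted p = 0.65). Named probes that did not pass included metallothionein Mta_oud at 0.73, the ad nucl translocase of the mitochondrial membrane at 0.60, acyl coa reductase at 1.35, cyplasin s Rep_ASP8 B4 at 1.59, cyclin b at 0.64, chromobox, a chromatin protein, at 0.40, and ferritine_oud at -0.13. In all, 3 of 30 named probes passed, 2 when adjusted over the list alone and 1 after centring. Of 2176 probes, 306 passed, 288 higher and 18 lower, but 201 after centring, 128 higher and 73 lower. Without a name, Mol_ASP8 E11 rose by 4.10 (adjusted p = 0.046, and 0.076 after centring), with means of 0.64 and -1.76 before removal of the dye coefficient. Rep_ASP7 F5 rose by 4.09 (SE 0.67, adjusted p = 0.0015), and Mol_ASP5 D3 and Mol_ASP4 C2 were at -2.87 and -2.82. The count was 1 when the sign of the Cy3 arrays was turned, 105 without the dye coefficient, 36 without Zn(+)F1 replicate 1, 73 without replicate 3, and 185 and 197 without CtrlF1 replicates 1 and 3. With the sign turned the vitellogenin probes were at -0.42 (vtg precursor) and -0.42 (vtg) and cyplasin s no longer passed, as without the dye coefficient (adjusted p = 0.13; 0.0015 to 0.23 over the alternatives). Without CtrlF1 replicates 1 and 2 the vitellogenin calls also ended, with adjusted p = 0.068 and 0.072 for Rep_ASP1 F6 and 0.11 and 0.065 for Rep_ASP1 H2.

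Zn(-)F1 against CtrlF1 asked what was left in offspring of exposed mothers that grew up in control medium. The cyplasin s probe Rep_ASP8 F6 rose here too, by 1.02 (SE 0.19, adjusted p = 0.0025), to 0.31 ± 0.071 (SD, n = 3) from -0.71 ± 0.035 in CtrlF1, or by 0.70 relative to the median of all probes, which was shifted by 0.33. Vitellogenin did not pass, with 0.62 for Rep_ASP1 F6 (SE 0.26, adjusted p = 0.11) and 0.55 for the precursor Rep_ASP1 H2 (SE 0.27, adjusted p = 0.18). Chromobox at 0.51, cyclin b at 0.74, cyplasin s Rep_ASP8 B4 at 2.00 and A4 at 0.65, metallothionein Mtb_oud at 0.55 and ferritine_oud at -0.14 did not pass either. The yolk and egg list had a median of 0.55 and an adjusted p of 0.65. In all, 1 of 30 named probes passed, 1 when adjusted over the list alone and 1 after centring. Of 2198 probes, 294 passed, 247 higher and 47 lower, but 230 after centring, 114 higher and 116 lower. Rep_ASP7 F5 rose again, by 3.79 (SE 0.62, adjusted p = 0.0014), and Mol_ASP6 H12 by 3.35, while Mol_ASP4 G5 was at -5.02 and Mol_ASP2 B1 at -4.39. The count was 7 with the sign of the Cy3 arrays turned, 149 without the dye coefficient, 587 with the arrays of the compared groups alone, and 192, 187, 157, 163 and 146 without CtrlF1 replicate 1, CtrlF1 replicate 2, CtrlF1 replicate 3, Zn(-)F1 replicate 2 and Zn(-)F1 replicate 3. The call of cyplasin s ended without the dye coefficient (adjusted p = 0.090) and with the sign turned (0.19), the range over the alternatives being 3.8e-04 to 0.19.

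Zn(+)F1 and Zn(-)F1 had the same mothers and differed in their own medium. No difference of a named probe passed: limma called 0 of 37, with 0 at an unadjusted p under 0.05 and 0 after centring. Metallothionein Mta_oud differed by 0.43 (SE 0.23), the vitellogenin precursor Rep_ASP1 H2 by 0.36 (SE 0.24), vtg Rep_ASP1 F6 by 0.32 (SE 0.23), rib 40S by 0.38, cyplasin s Rep_ASP8 A4 by -0.35, ferritine_bis by 0.28 and ad nucl translocase by 0.19, each with an adjusted p of 1. With the sign of the Cy3 arrays turned these differences change sign, since both groups carried Cy3. Of 2208 probes 1 passed, Ene_ASP4 C9, higher by 0.99 in Zn(+)F1 (SE 0.15, adjusted p = 0.0070), and 84 had an unadjusted p under 0.05. The 2 groups shared 185 probes that were higher than in CtrlF1 and 13 that were lower, where lists of the same sizes from simulated unchanged groups against those shared CtrlF1 arrays gave means of 122 and 7.58 (highest 140 and 13), and independent lists 32.1 and 0.39. After centring they shared 75 and 52, against 6.67 and 3.91 for independent lists. The count was 0 without Zn(+)F1 replicate 2, 0 without Zn(-)F1 replicate 3, 4 without Zn(-)F1 replicate 2 and up to 8 with array weights.

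Zn(+)F2 against CtrlF2 asked what zinc kept on into the F2 generation changed. No named probe passed: limma called 0 of 40, with 5 at an unadjusted p under 0.05, 0 when adjusted over the list alone and 1 after centring. The one of smallest p was acyl coa reductase Rep_ASP1 E5, of lipid metabolism, at 1.00 ± 0.84 in Zn(+)F2 and -0.91 ± 0.86 in CtrlF2 (SD, n = 3 each), a log2 change of 1.91 (SE 0.50, adjusted p = 0.053) that passed after centring (adjusted p = 0.019; 0.015 to 0.97 over the alternatives). Vitellogenin stood at 0.62 ± 0.20 against 0.09 ± 0.26 (Rep_ASP1 F6) and 0.64 ± 0.19 against 0.11 ± 0.31 (precursor Rep_ASP1 H2), changes of 0.53 and 0.53 with adjusted p = 0.19 and 0.21. In the yolk and egg list, with a median of 0.53, no member passed over all probes and 2 of 3 did when adjusted over the list alone; the list test gave an adjusted p of 0.42. A ferritine probe was at 2.12 (SE 0.93; n = 2 and an SD of 2.33 in Zn(+)F2), cyplasin s Rep_ASP8 A5 at -1.71, rib 40S at -0.63 and metallothionein Mtb_bis at 0.36, and none passed. Another probe named ferritine stood at 1.64 ± 3.29 against 1.21 ± 2.82 in CtrlF2 (SD, n = 3 each). Of 2242 probes, 58 passed, 43 higher and 15 lower, with a median of all probes of 0.11; after centring 124 did, 74 higher and 50 lower. Mol_ASP6 E1 rose by 5.23 (SE 0.35, adjusted p = 3.8e-08), from 0.72 ± 0.20 to 5.94 ± 0.38 before removal of the dye coefficient, and Rep_ASP8 E1 by 6.20 with an SD of 4.94 between the Zn(+)F2 arrays. Rep_ASP2 A1 was at -6.22 and Mol_ASP4 A6 at -4.60, with SDs of 6.67 (n = 2) and 3.31 (n = 3) between the Zn(+)F2 arrays. The count was 283 without Zn(+)F2 replicate 3, 183 without CtrlF2 replicate 3, 105 without Zn(+)F2 replicate 1, 126 with the sign of the Cy3 arrays turned and 1 with the arrays of the compared groups alone. Acyl coa reductase passed without CtrlF2 replicate 2 (adjusted p = 0.048), CtrlF2 replicate 3 (0.022) or Zn(+)F2 replicate 3 (0.0050).

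Zn(+/-)F2 against CtrlF2 asked what remained after 2 exposed generations and a return to control medium. No named probe passed: limma called 0 of 40, with 1 at an unadjusted p under 0.05 and 0 after centring. Vitellogenin was at -0.31 ± 0.37 (Rep_ASP1 F6) and -0.32 ± 0.48 (precursor Rep_ASP1 H2) in Zn(+/-)F2, changes of -0.40 and -0.44 (SE 0.21 and 0.22, adjusted p = 0.45 and 0.42), and the yolk and egg list had a median of -0.40 (adjusted p = 0.24). Rib 40S at -0.73, ferritine_oud at -0.47, nucleosome assembly at -0.31, metallothionein Mta_bis at -0.34 and acyl coa reductase at 0.79 did not pass. Of 2244 probes, 33 passed, 22 higher and 11 lower, and 64 after centring, 46 higher and 18 lower. Ene_ASP2 G11 rose by 5.32 (SE 0.84, adjusted p = 0.0076) and Mol_ASP3 H3 by 3.71 (SE 0.83, adjusted p = 0.028), while Mol_ASP6 B1 and Rep_ASP2 G3 were at -1.51 and -1.24. Both of the risen probes stood low in CtrlF2 itself, at -5.68 ± 1.57 and -4.37 ± 1.06 (SD, n = 3). The count was 6 without Zn(+/-)F2 replicate 2, 64 and 62 without CtrlF2 replicates 2 and 3, 143 with the sign of the Cy3 arrays turned and 6 with the arrays of the compared groups alone. The excess of higher calls turned over without Zn(+/-)F2 replicate 3 (9 higher and 20 lower) and with the sign turned (0 and 143). Without Zn(+/-)F2 replicate 3 the vitellogenin precursor was at -0.89 and passed (adjusted p = 0.043).

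Zn(-/-)F2 against CtrlF2 asked what remained after 2 generations in control medium. Here 2 of the 3 vitellogenin probes were lower than in any other group: Rep_ASP1 F6 stood at -0.95 ± 0.13 against 0.09 ± 0.26 in CtrlF2, and the precursor Rep_ASP1 H2 at -1.07 ± 0.13 against 0.11 ± 0.31 (SD, n = 3 each). The first fell by 1.04 (SE 0.21, adjusted p = 0.0031) and the second by 1.19 (SE 0.22, adjusted p = 0.0016), and at both the 3 Zn(-/-)F2 arrays lay below the 3 CtrlF2 arrays. Arrays of these groups did not overlap at 23.8% of all tested probes. Of the 3 members of the yolk and egg list 2 fell, also when adjusted over the list alone, and Rep_ASP1 G1 was at -0.21 (SE 0.18). The list test (cameraPR) passed, with a median of -1.04 and an adjusted p of 9.4e-04 at the preset correlation of 0.01. With the correlation estimated at 0.49 the adjusted p was 0.033. This test rests on the 2 called probes and is no separate support for them. In all, 2 of 40 named probes passed, 2 when adjusted over the list alone and 5 after centring. Rib 40S at -0.83 and nucleosome assembly, which places histones on DNA, at -0.41 passed after centring (adjusted p = 0.025 and 0.0096; 0.025 to 0.81 and 0.0088 to 0.82 over the alternatives). Acyl coa reductase at 1.06, rib 16S at 0.54 (Rep_ASP1 B5) and 0.41 (Rep_ASP8 F4), az aminotransferase at 0.44, ferritine_oud at -0.40 and metallothionein Mtb_bis at 0.42 did not pass. Of 2245 probes, 224 passed, 111 higher and 113 lower, with a median of all probes of 0.12; after centring 396 did, 156 higher and 240 lower. Ene_ASP2 G11 rose by 5.50 and Mol_ASP3 H3 by 4.06, both from the low CtrlF2 values, while Ene_ASP7 G1 was at -1.69 (SE 0.38, adjusted p = 0.0073). The count was 114, 129 and 416 without Zn(-/-)F2 replicates 1, 2 and 3, and 5 with the arrays of the compared groups alone, which also ended both vitellogenin calls (adjusted p = 0.21; 6.8e-05 to 0.71 for the precursor and 1.1e-04 to 0.89 for Rep_ASP1 F6 over the alternatives). The changes themselves stayed at -1.04 and -1.19 there. The list, which rests on the same probes, passed at the preset correlation of 0.01 (cameraPR adjusted p = 0.0090), and the estimated correlation was not tried there. With the sign of the Cy3 arrays turned, these probes were at 0.10 (Rep_ASP1 F6) and 0.25 (Rep_ASP1 H2), without passing, and the list test gave an adjusted p of 0.44, but as deposited the Cy3 and Cy5 arrays ran the same way within Zn(-/-)F2 (r = 0.413 and 0.757) and within CtrlF2 (0.273 and 0.274), which goes against that turn. The balance of calls was 233 higher and 82 lower without CtrlF2 replicate 3, 321 and 95 without Zn(-/-)F2 replicate 3, and 355 and 91 with array weights. It was 56 and 112 without CtrlF2 replicate 1, 42 and 72 without Zn(-/-)F2 replicate 1, 42 and 87 without its replicate 2, and 1 and 286 with the sign turned. Without CtrlF2 replicate 3, az aminotransferase (adjusted p = 0.032) and rib 16S Rep_ASP8 F4 (0.034) passed, and without Zn(-/-)F2 replicate 3 so did az aminotransferase (0.015), Rep_ASP8 F4 (0.036) and acyl coa reductase (0.032).

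**Figure D2:**
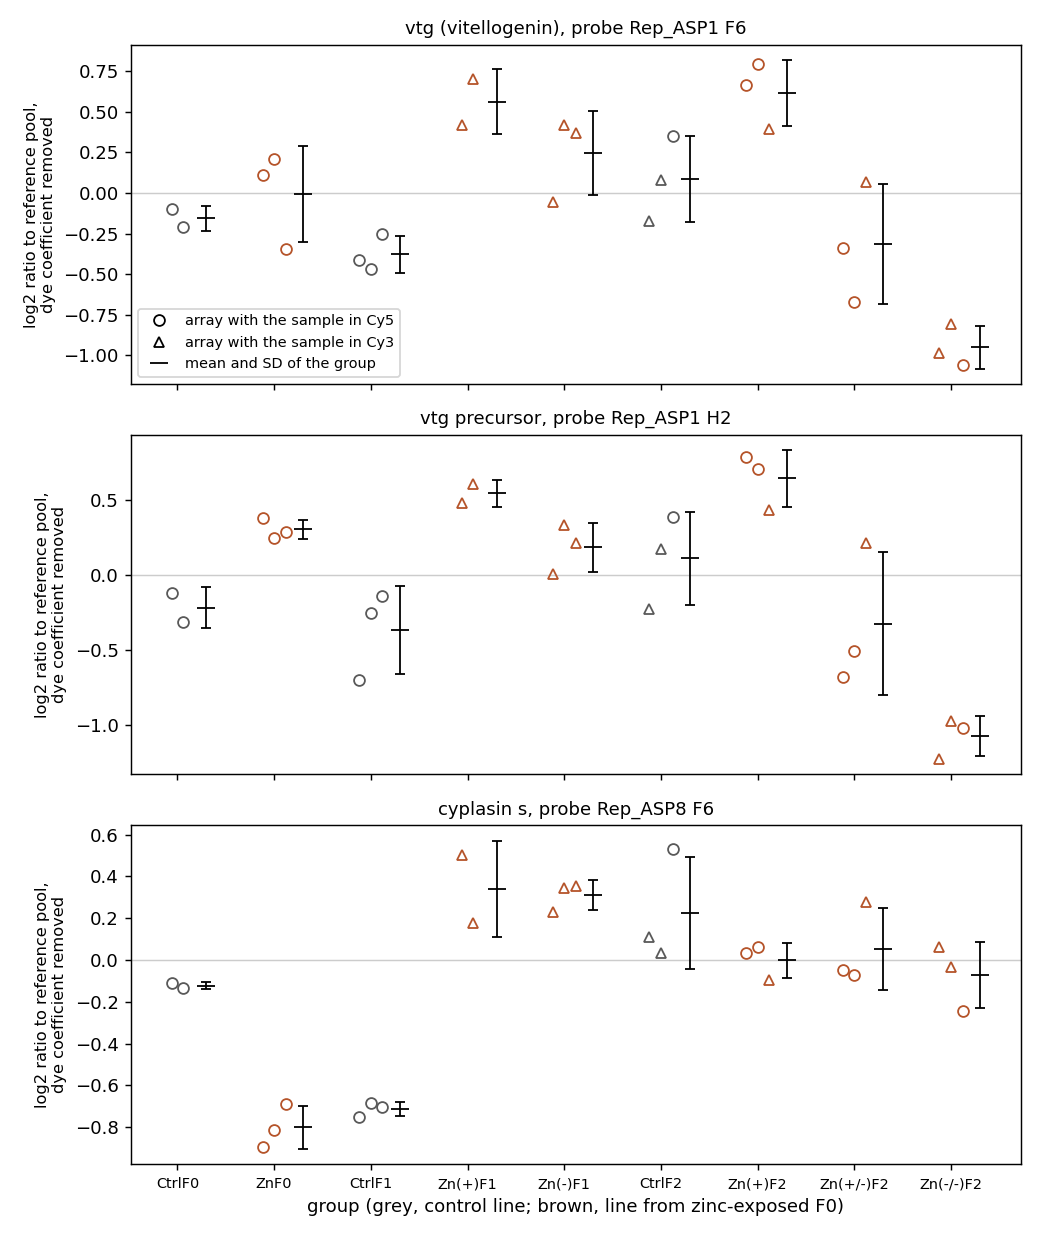
Log2 ratio to the reference pool after removal of the dye coefficient (vertical axis) for 3 named probes by group (horizontal axis); circles and triangles are single arrays with the sample in Cy5 and Cy3, and bars give the mean and SD. Both vitellogenin probes are lowest in Zn(-/-)F2 (-0.95 and -1.07), and cyplasin s is low in ZnF0 (-0.80) and CtrlF1 (-0.71).

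Zn(+)F2 and Zn(+/-)F2 had the same mothers and differed in their own medium, but also in age, at 21 and 22 days. Medium and age cannot be told apart here. Vitellogenin was higher in the animals kept in zinc, by 0.93 for Rep_ASP1 F6 (SE 0.21, adjusted p = 0.017), at 0.62 ± 0.20 against -0.31 ± 0.37, and by 0.97 for the precursor Rep_ASP1 H2 (SE 0.22, adjusted p = 0.017), at 0.64 ± 0.19 against -0.32 ± 0.48 (SD, n = 3 each). Of the 3 members of the yolk and egg list 2 were higher, also when adjusted over the list alone, Rep_ASP1 G1 being at 0.32 (SE 0.18). The list test (cameraPR) passed, with a median of 0.93 and an adjusted p of 0.0017 at the preset correlation of 0.01. With the correlation estimated at 0.49 the adjusted p was 0.046. This test rests on the 2 called probes and is no separate support for them. In all, 2 of 40 named probes passed, 2 when adjusted over the list alone and 2 after centring. A ferritine probe at 2.21 (n = 2 in Zn(+)F2), acyl coa reductase at 1.11, cyplasin s Rep_ASP8 A5 at -1.39, histone deacetylase, which removes acetyl groups from histones, at 0.92, metallothionein Mtb_bis at 0.71 and a proteasome subunit at 0.47 did not pass. Another probe named ferritine stood at 1.64 ± 3.29 against -0.30 ± 1.64 (SD, n = 3 each). Of 2237 probes, 94 passed, 81 higher and 13 lower in Zn(+)F2, and 135 after centring, 94 higher and 41 lower. Mol_ASP6 E1 rose by 5.30 (SE 0.34, adjusted p = 1.8e-08) and Rep_ASP8 E1 by 6.01, while Ene_ASP2 F9 was at -3.86 and Mol_ASP4 A6 at -3.32. Before removal of the dye coefficient, SDs between the Zn(+)F2 arrays were 0.38, 4.94, 4.09 and 3.31 in that order. The count was 6 and 7 without Zn(+/-)F2 replicates 2 and 1, 152 and 260 without Zn(+)F2 replicates 1 and 3, 5 without the dye coefficient, 2 with the arrays of the compared groups alone and 519 with the sign of the Cy3 arrays turned. Both vitellogenin calls ended without the dye coefficient (adjusted p = 0.094 and 0.098; 0.0051 to 0.80 and 0.0054 to 0.80 over the alternatives), with the arrays of the compared groups alone (0.80), with the sign turned (0.18 and 0.15) and without either of those Zn(+/-)F2 replicates (0.077 to 0.11). Without the dye coefficient or with the compared arrays alone only the error moved: the changes stayed at 0.93 and 0.97. The list, which rests on the same probes, passed at the preset correlation of 0.01 (cameraPR adjusted p = 0.0040 and 0.0081), and the estimated correlation was not tried there. The call of Rep_ASP1 F6 also ended without Zn(+)F2 replicate 2 (adjusted p = 0.056), and that of the list without Zn(+)F2 replicate 3 (0.053) and with the sign turned (0.85). As deposited, Cy3 and Cy5 arrays ran the same way within Zn(+/-)F2 (r = 0.344 and 0.434). In Zn(+)F2 r was 0.030 and -0.127, so the direction of its Cy3 array stays open. Without Zn(+)F2 replicate 3, acyl coa reductase (adjusted p = 0.031) and histone deacetylase, then at 1.85, passed.

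**Figure D3:**
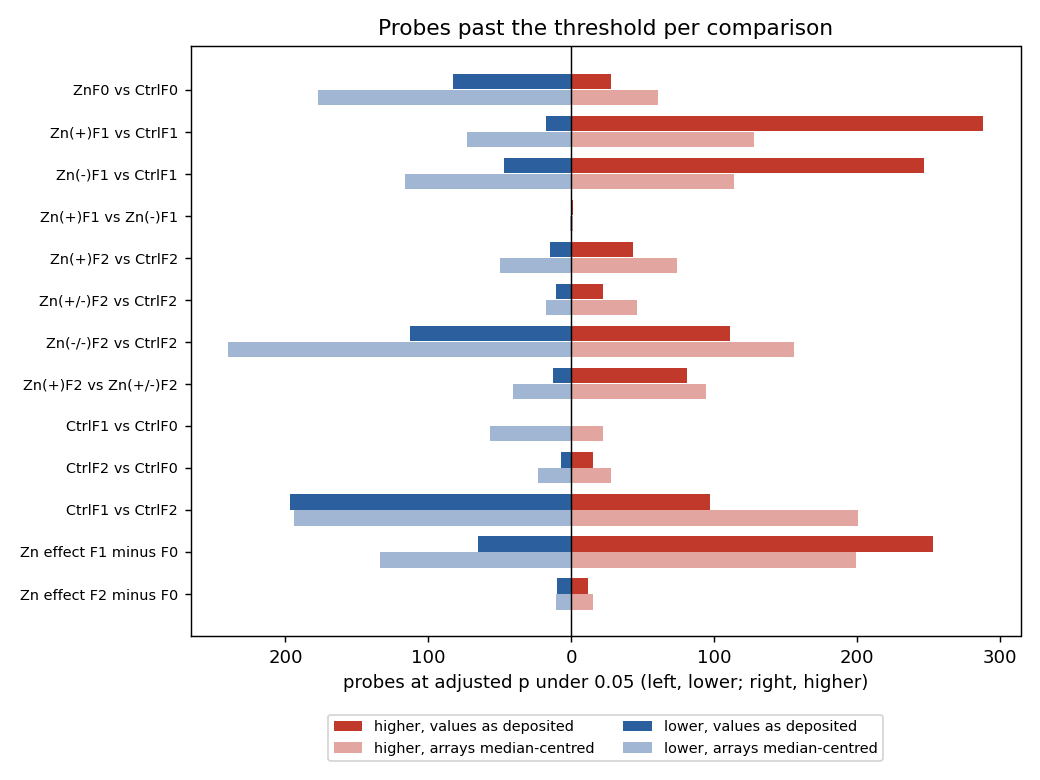
Number of probes at an adjusted p under 0.05 (horizontal axis, bars from 0, lower to the left and higher to the right) per comparison (vertical axis), dark for the values as deposited and light after median-centring of every array. Zn(+)F1 against CtrlF1 goes from 288 higher and 18 lower to 128 and 73, and Zn(-)F1 against CtrlF1 from 247 and 47 to 114 and 116.

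The other lists did not pass in any comparison of exposure in which they had 3 or more measured members. For metallothionein, the 6 probes of the metal and redox defence list, medians ran from -0.17 in Zn(+/-)F2 (adjusted p = 0.26) to 0.28 in Zn(+)F2 against Zn(+/-)F2 (0.37), with 0.06 in ZnF0 (0.92), 0.21 in Zn(-/-)F2 (0.73), 0.10 in Zn(+)F2 (0.96) and -0.06 between the F1 groups (0.68). In Zn(+)F2 the sign of the test was downward although all 6 changes were positive, because the median of all probes was 0.11. Ferritin, the globins and iron list, had medians of -0.13 in ZnF0 (0.92), 0.32 in Zn(+)F2 (0.96), -0.36 in Zn(+/-)F2 (0.26), -0.32 in Zn(-/-)F2 (0.65) and 1.20 in Zn(+)F2 against Zn(+/-)F2 (0.26). Chromatin and methylation (nucleosome assembly, chromobox and histone deacetylase) had medians of 0.19 in ZnF0 (0.92), where the test pointed down, 0.40 in Zn(+)F1 (0.94), 0.51 in Zn(-)F1 (0.65), -0.05 between the F1 groups (0.48), -0.09 in Zn(+)F2 (0.96), where the mean was 0.11, -0.31 in Zn(+/-)F2 (0.26), -0.10 in Zn(-/-)F2 (0.48) and 0.19 in Zn(+)F2 against Zn(+/-)F2 (0.58). Vitellogenin, as the yolk and egg list, had a median of 0.32 between the F1 groups (0.48). The 5 cyplasin s probes, a list chosen after their values were seen, had an unadjusted camera p of 0.057 in Zn(-)F1, 0.25 in Zn(+)F1 and 0.59 in ZnF0, where the median was 0.28 but the test pointed down. All told 2 of 26 list tests passed, both for yolk and egg. With fry, which tests probes without reference to others and here ran on 2 vitellogenin probes alone, Rep_ASP1 F6 and H2 without G1, 4 passed, with Zn(+)F1 (adjusted p = 0.0077) and Zn(+)F2 (0.048) added. Both added results include the shift of all probes, with medians of 0.36 and 0.11.

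Control lines also changed between generations. The cyplasin s probe Rep_ASP8 F6 was lower in CtrlF1 than in CtrlF2, by -0.94 (SE 0.17, adjusted p = 0.0031), at -0.71 ± 0.035 against 0.22 ± 0.27 (SD, n = 3 each), and 1 of 30 named probes passed there, 1 when adjusted over the list alone and 2 after centring. This call ended without the dye coefficient (adjusted p = 0.053; 5.2e-04 to 0.40 over the alternatives), with the arrays of the compared groups alone (0.40) and without CtrlF2 replicate 3 (0.052). Vitellogenin Rep_ASP1 F6 was at -0.46 (SE 0.23, adjusted p = 0.21), metallothionein Mtb_oud at -0.29 and ferritine_oud at -0.22 in the same comparison. For CtrlF2 against CtrlF0, limma called 0 of 29 named probes, with 3 at an unadjusted p under 0.05 and 0 after centring; rib 40S, at 1.37 (SE 0.37), passed when adjusted over the list alone (1 probe, named after its value was seen) and not over all probes (adjusted p = 0.073). The vitellogenin precursor was at 0.33, Mtb_oud at 0.45 and ferritine_oud at 0.41 there. Between CtrlF1 and CtrlF0, limma called 0 of 25 named probes, with 2 at an unadjusted p under 0.05 and 1 after centring. That one was cyplasin s Rep_ASP8 F6, at -0.59 as deposited (SE 0.17, adjusted p = 0.14) and -0.60 after centring (adjusted p = 0.014). Vtg Rep_ASP1 F6 was at -0.22, Mtb_oud at 0.16 and ferritine_oud at 0.19. By comparison, 294 of 2207 probes passed for CtrlF1 against CtrlF2 (97 higher and 197 lower, median of all probes -0.13; 395 after centring, 201 higher and 194 lower), led by Mol_ASP3 H3 at 5.08 and Ene_ASP1 A3 at -3.09 (SE 0.97, adjusted p = 0.044). Its excess of lower calls turned over without the dye coefficient (137 higher and 31 lower), with the arrays of the compared groups alone (55 and 3), with array weights (227 and 30) and without CtrlF2 replicate 3 (56 and 19). For CtrlF2 against CtrlF0 22 of 2007 passed (15 higher and 7 lower; 51 after centring, 28 higher and 23 lower), led by Rep_ASP3 B2 at 2.00 and Ene_ASP2 G11 at -5.19; the balance was 3 higher and 10 lower without the dye coefficient, 5 and 30 with array weights, and 2 and 11 without CtrlF2 replicate 3. For CtrlF1 against CtrlF0 limma called 0 of 1996, with 250 at an unadjusted p under 0.05, 79 after centring and 132 with array weights. Without CtrlF2 replicate 3 the first of these counts was 75, and without CtrlF1 replicates 1, 2 and 3 it was 168, 153 and 119; the second was 1 without the averaged CtrlF0 array, 37 without CtrlF0 replicate 2, and 56, 53 and 13 without CtrlF2 replicates 1, 2 and 3; the third was 10 without CtrlF0 replicate 2 and 3 without CtrlF1 replicate 2.

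The effect of zinc was compared directly between generations. The cyplasin s probe Rep_ASP8 F6 had differences from the control of opposite sign, that of Zn(+)F1 exceeding that of ZnF0 by 1.73 (SE 0.26, adjusted p = 5.4e-04), or 1.35 relative to the shift of all probes, and it passed in all 12 alternatives. With each of 9 arrays left out in turn the difference ran from 1.69 to 1.79. Zn(+)F1 replicates 1 and 3, the only ones with a value for this probe, could not be left out. The controls themselves stood at -0.12 in CtrlF0 and -0.71 in CtrlF1, a difference that was not called as deposited. Zn(-)F1, reared in control medium, was higher than CtrlF1 by 1.02, a limma call that ended with the sign of the Cy3 arrays turned (adjusted p = 0.19). Whether the difference comes from the animals' own exposure was therefore not settled. Vitellogenin Rep_ASP1 F6 differed by 0.79 (SE 0.36, adjusted p = 0.15; -0.57 with the sign of the Cy3 arrays turned), metallothionein Mta_oud by 0.65 (SE 0.37) and ferritine_oud by 0.004 (SE 0.39). In all, 1 of 25 named probes passed, 1 when adjusted over the list alone and 1 after centring. Of 1962 probes, 318 passed, 253 higher and 65 lower, with a median of all probes of 0.38; after centring 333 did, 199 higher and 134 lower, and without the dye coefficient the balance was 88 and 91. Rep_ASP7 F5 was higher by 4.92 and Mol_ASP6 H12 by 4.52, while Mol_ASP4 H11 and Mol_ASP4 G5 were at -5.34 and -5.33. Between F2 and F0 limma called 0 of 29 named probes, with 2 at an unadjusted p under 0.05 and 0 after centring: vtg Rep_ASP1 F6 differed by 0.39 (SE 0.31), ferritine_bis by 0.35 and metallothionein Mta by 0.16. Of 1980 probes, 22 passed, 12 higher and 10 lower, and 26 after centring, Mol_ASP6 E1 being higher by 5.42 (SE 0.51, adjusted p = 8.6e-06), Mol_ASP6 E6 by 2.71 (adjusted p = 0.033, and 0.066 after centring), Mol_ASP6 C1 at -2.85 and Rep_ASP5 G5 at -1.84. The count for F1 was 187 without the averaged CtrlF0 array and 113 and 137 without Zn(+)F1 replicates 1 and 3. That for F2 was 6, 7 and 8 without the averaged CtrlF0 array, ZnF0 replicate 1 and ZnF0 replicate 3, 37 without CtrlF2 replicate 3 or Zn(+)F2 replicate 1, and 76 without Zn(+)F2 replicate 3.

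Whole profiles were then compared, across probes, which are not independent replicates. The 2 F1 effects correlated with a Spearman's rho of 0.894 (0.609 in simulated unchanged groups with the same shared control; covariance 0.642, simulated 0.19). Zn(+/-)F2 and Zn(-/-)F2 correlated with 0.842 (simulated 0.447; covariance 0.380, simulated 0.105). The draws gave all arrays 1 spread per probe, while CtrlF2 arrays had SDs of 0.63 to 1.15 and arrays of these 2 groups 0.26 to 0.47. Simulated values can thus be too low where CtrlF2 is shared, and part of the excess can come from that control. All 22 probes higher in Zn(+/-)F2 were also higher in Zn(-/-)F2, and 10 of its 11 lower probes were lower there (41 and 16 shared after centring). Simulated unchanged groups against the shared CtrlF2 arrays gave means of 8.48 and 5.16 for lists of those sizes (highest 13 and 9), and independent lists 1.08 and 0.55; the controls could not be split, and part of the excess can come from them. Zn(+)F2 correlated with these at 0.446 and 0.392, below the simulated 0.491 and 0.447 (SD 0.018 each), with covariances of 0.253 and 0.210 (simulated 0.117 and 0.111). The ZnF0 effect, which shares no array with the others, had a rho of 0.287 to 0.333 with the F2 effects and of -0.219 and -0.294 with the F1 effects. With the sign of the Cy3 arrays turned its rho with Zn(+)F2, Zn(+/-)F2 and Zn(-/-)F2 was 0.031, -0.123 and -0.223. Over 15 pairs of effects the median rho was -0.070, from -0.355 to 0.894, and the simulated median was -5.7e-04 with an SD of 0.011. Single ZnF0 arrays resembled CtrlF1 arrays (mean r = 0.569, 9 pairs) more than CtrlF0 arrays (mean r = 0.040, 6 pairs), and Zn F1 arrays ran opposite to CtrlF1 (mean r = -0.331, 15 pairs).

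**Figure D4:**
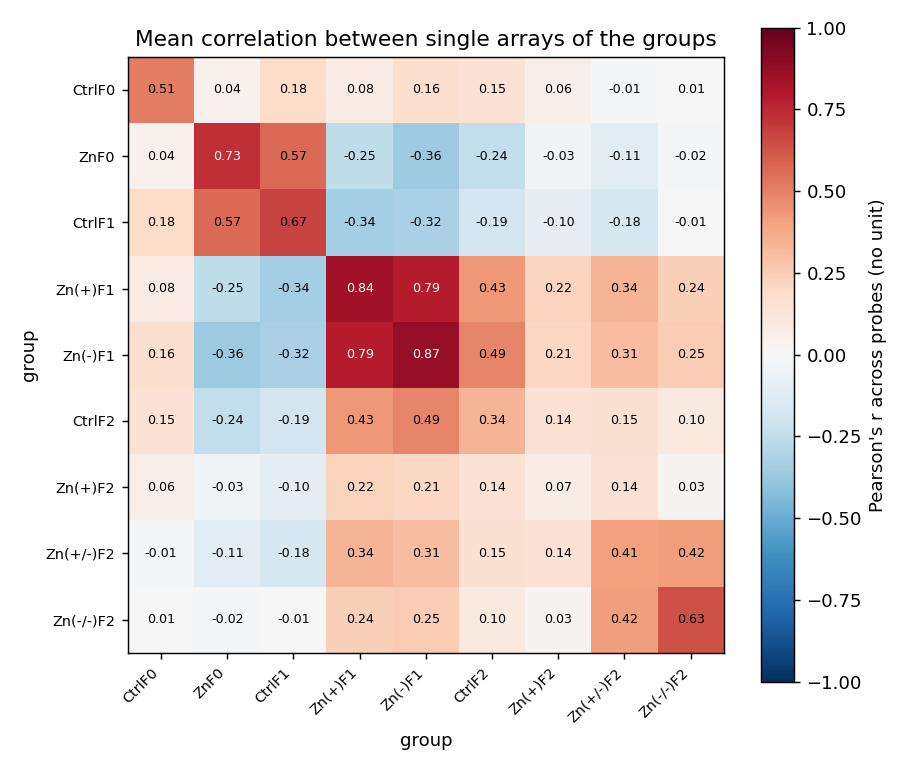
Mean Pearson's r across probes between single arrays of each pair of groups (both axes; colour from -1 to 1), without Zn(+)F1 replicate 2; the diagonal gives pairs of different arrays within a group. ZnF0 and CtrlF1 share a mean r of 0.569 and Zn(+)F1 and CtrlF1 one of -0.344.

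The authors' deposited tables gave more calls for the same comparisons. For ZnF0 against CtrlF0 the authors' deposited table called 738 probes, 374 of them higher, with log2 changes that correlated with those of the fit at r = 0.963 across probes and 109 of the fit's 111 calls included. In that table cyplasin s Rep_ASP8 F6 was at -0.69 (adjusted p = 6.6e-07), the vitellogenin precursor Rep_ASP1 H2 at 0.67 (4.7e-06), nucleosome assembly at -0.38 (6.8e-04), a kinase at 0.37 (0.019) and cyclin b3 at -0.32 (0.020). For CtrlF1 against CtrlF0 the authors' deposited table called 557 probes, with cyplasin s Rep_ASP8 F6 at -0.57 (1.4e-05), vtg Rep_ASP1 F6 at -0.45 (0.011) and ferritine_oud at 0.22 (5.7e-04). For CtrlF1 against CtrlF2 it called 691, including 221 of the fit's 294, and for CtrlF2 against CtrlF0 279, including 6 of 22. With CtrlF0 replicates 1 and 3 as 2 samples the fit called 265 for ZnF0 and 85 for CtrlF1 against CtrlF0. In this fit, equal columns counted as separate thus leave most of the gap unexplained. In the authors' changes for ZnF0, the regression gave the repeated column a weight of -0.336 and CtrlF0 replicate 2 one of -0.659. Equal columns counted as 2 samples would give the repeated column the larger weight, so the authors' fit does not look to have held them so.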

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

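The tests of the equal CtrlF0 columns, of age for ZnF0 and CtrlF1, and of the direction of the Cy3 arrays were chosen after the results were seen. Cyplasin s Rep_ASP8 F6 stands here because its difference from the control of the same generation differed by 1.73 (log2) between F1 and F0 in a test of the difference itself. The same test called 318 probes between F1 and F0 and 22 between F2 and F0.

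ZnF0 arrays resembled CtrlF1 arrays, with a mean r of 0.569 across probes over 9 pairs, and not CtrlF0 arrays, with 0.040 over 6. The equal CtrlF0 columns enter none of the 9 pairs with CtrlF1 (r from 0.357 to 0.751) and do not bear on that likeness, but for the low r with CtrlF0 they stay open, as the 1 array that is not repeated had a mean r of 0.068 over 3 pairs and a single array excludes nothing. Age alone did not make arrays alike: the F2 arrays of 22 days had a mean r of -0.079 with ZnF0 and CtrlF1 arrays (36 pairs, SD 0.148, from -0.257 to 0.277). Those F2 arrays also differ in generation, ancestry and in part in dye, so a share of age in the likeness stays open. A common processing batch stays open: missing spots overlapped by 0.0224 more between ZnF0 and CtrlF1 than between ZnF0 and CtrlF0, with an SD of 0.0634 over pairs, and the labels give no batch. Exposure itself is not shared by CtrlF1, and no biological explanation of the likeness was tested.

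Zn(+)F1 and Zn(-)F1, with cyplasin s Rep_ASP8 F6 higher in both, differed from CtrlF1 and hardly from each other, and both were in Cy3 where CtrlF1 was in Cy5. Dye effects of single probes would have made the F1 difference without a dye coefficient run against Cy5 minus Cy3 in Zn(+/-)F2 and Zn(-/-)F2. No such opposite run was seen, with a mean Pearson correlation of 0.277 and Spearman's rho of 0.109 in Zn(+)F1 and 0.138 in Zn(-)F1. But each of these 2 groups set 1 array of one dye against 2 of the other, so differences between replicates enter as well. The test therefore cannot exclude dye effects. The uncentred CtrlF2 and Zn(+)F2 were not used. The excess of higher calls may come from the uncentred CtrlF2 and Zn(+)F2 arrays behind the dye coefficient, as the share of higher calls in Zn(+)F1 went from 94.1% to 63.7% with all arrays median-centred and to 49.7% with those arrays left out. The direction in which the Cy3 arrays were deposited stays open, since turning it left 1 call in Zn(+)F1 and 7 in Zn(-)F1; as deposited, Zn F1 arrays had a mean r of -0.331 with CtrlF1 arrays and 0.398 with the Cy5 array of CtrlF2. Exposure of the mothers, the biological explanation that the design offers, cannot be told apart from that direction or from dye effects, because no F1 group held both dyes.

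Vitellogenin Rep_ASP1 F6 and H2 were lower in Zn(-/-)F2 than in CtrlF2, by -1.04 and -1.19. The offsets of the uncentred CtrlF2 arrays as the whole cause are argued against by the median change of all probes, 0.12, which is opposite to the fall. Median-centring could therefore only shift these changes further down and decides nothing more. The higher limma adjusted p of both probes after it was 1.1e-04 (6.8e-05 to 0.89 over the alternatives of both). Centring leaves the spread of the CtrlF2 arrays as it was. Age stays open, with 22 days in Zn(-/-)F2 and 20 in CtrlF2: across 9 groups the relation of vitellogenin to age, the 1 computed, had a Spearman's rho of -0.338 (exact permutation p = 0.374) and an r of -0.304 (exact permutation p = 0.431), and r was -0.662 without ZnF0, farthest from the median age, and CtrlF0, which is no farther than 4 others. The other groups of 22 days stood at -0.37 (CtrlF1) and -0.32 (Zn(+/-)F2), against -1.01 in Zn(-/-)F2, while ZnF0 at 23 days stood at 0.15. Phase of the brood cycle was not recorded in the labels, and the exposure of grandmothers stays an untested explanation.

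With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. In both comparisons of an F1 group with CtrlF1, only the real split parts all Cy5 arrays from all Cy3 arrays. Its counts there cannot tell an effect of group from one of dye. The real split and the highest other gave 306 and 8 probes in Zn(+)F1 against CtrlF1, 294 and 0 in Zn(-)F1 against CtrlF1, 1 and 2 in Zn(+)F1 against Zn(-)F1, 33 and 19 in Zn(+/-)F2 against CtrlF2, 224 and 38 in Zn(-/-)F2 against CtrlF2, and 294 and 0 in CtrlF1 against CtrlF2. In Zn(+)F2 against CtrlF2 they gave 58 and 1123, and 3 of the 10 splits gave as many as the real one. The split with 1123 parts all Cy3 arrays, with medians of -0.33 and -0.40, from all Cy5 arrays, with 0.35 and 0.32. In Zn(+)F2 against Zn(+/-)F2 they gave 94 and 388, the latter with the Cy3 arrays of both groups exchanged. That split sets the Cy5 arrays of Zn(+)F2 against its Cy3 array, whose median has the other sign. Splits were run on the values as deposited, so both high counts may come from the offsets of the uncentred arrays.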

How the results depend on the processing

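Median-centring alone, CtrlF0 replicates 1 and 3 as 2 samples, values beyond 5 set to missing, and the runs without the 6 uncentred arrays or without the Zn(+)F1 replicate 2 array were chosen after the data were seen; the other settings were planned. Cyplasin s Rep_ASP8 F6 passed for the difference between F1 and F0 in all 12 alternatives, with adjusted p from 5.0e-05 to 0.019. There were 87 named results, each a named probe or a list in 1 comparison, so that a probe can be counted more than once. Over these, 885 values under other settings kept their direction and side of the threshold. Another 29 no longer passed, 25 passed in addition and 60 reversed, that is changed sign, most of them passing under neither setting. With a replicate left out these counts were 449, 15, 13 and 11. Robust eBayes left the 13 counts of probes within 1.5 times. Where a smaller number of probes or arrays does not explain a move below, the cause was not tested. With no dye coefficient the counts were 29 in ZnF0 against CtrlF0, 105 in Zn(+)F1, 149 in Zn(-)F1, 0 between Zn(+)F1 and Zn(-)F1, 5 between Zn(+)F2 and Zn(+/-)F2, 13 for CtrlF2 against CtrlF0, 168 for CtrlF1 against CtrlF2, 179 for F1 minus F0 and 13 for F2 minus F0. The setting with only the arrays of the groups compared also had no dye coefficient. Its counts were 230 in ZnF0, 587 in Zn(-)F1, 1 in Zn(+)F2, 6 in Zn(+/-)F2, 5 in Zn(-/-)F2, 2 between Zn(+)F2 and Zn(+/-)F2, 3 for CtrlF2 against CtrlF0, 58 for CtrlF1 against CtrlF2 and 1 for F2 minus F0. With no dye coefficient, over all arrays or with these arrays alone, cyplasin s Rep_ASP8 B4 was at -0.44 in Zn(+)F1. These 2 settings also reversed Rep_ASP8 B4 to -0.04 and vtg precursor Rep_ASP1 H2 to -0.006 in Zn(-)F1, and Rep_ASP1 H2 to -0.038 for CtrlF2 against CtrlF0. They turned Mtb_oud to 0.028 for CtrlF1 against CtrlF2 and ferritine_oud to -0.25 for F1 minus F0, and left chromobox in Zn(+)F1 at 0 after rounding. With arrays median-centred and scaled they were 215 in ZnF0, 3 between Zn(+)F1 and Zn(-)F1, 109 in Zn(+/-)F2, 405 in Zn(-/-)F2, 151 for CtrlF1 against CtrlF0, 53 for CtrlF2 against CtrlF0 and 449 for CtrlF1 against CtrlF2, and ferritine_oud for F1 minus F0 was at -0.356. With median-centring only they were 238 in ZnF0, 201 in Zn(+)F1, 2 between Zn(+)F1 and Zn(-)F1, 124 in Zn(+)F2, 64 in Zn(+/-)F2, 396 in Zn(-/-)F2, 79 for CtrlF1 against CtrlF0 and 51 for CtrlF2 against CtrlF0, and the same ferritine_oud value was -0.294. With only probes measured on all arrays, fewer probes being tested and no list reaching 3 members, they were 48 in ZnF0, 67 in Zn(+)F1, 86 in Zn(-)F1, 9 in Zn(+)F2, 6 in Zn(+/-)F2, 65 in Zn(-/-)F2, 1 between Zn(+)F2 and Zn(+/-)F2, 3 for CtrlF1 against CtrlF0, 7 for CtrlF2 against CtrlF0, 95 for CtrlF1 against CtrlF2, 136 for F1 minus F0 and 6 for F2 minus F0. With array weights they were 337 in ZnF0, 8 between Zn(+)F1 and Zn(-)F1, 129 in Zn(+)F2, 70 in Zn(+/-)F2, 446 in Zn(-/-)F2, 132 for CtrlF1 against CtrlF0, 35 for CtrlF2 against CtrlF0 and 144 for F2 minus F0. The weights reversed cyplasin s Rep_ASP8 B4 in Zn(+)F1 to -0.029, ferritine_bis between Zn(+)F1 and Zn(-)F1 to -0.032, Mta_bis in Zn(+/-)F2 to 0.138 and ferritine_oud for F1 minus F0 to -0.259. For CtrlF2 against CtrlF0 they reversed Mtb_oud to -0.023 and vtg precursor Rep_ASP1 H2 to -0.029, and for CtrlF1 against CtrlF2 Mtb_oud to 0.179. With a replicate block they were 37 in ZnF0, 2 between Zn(+)F1 and Zn(-)F1, 7 for CtrlF2 against CtrlF0 and 14 for F2 minus F0, and within 1.5 times elsewhere, such as 261 in Zn(+)F1, 234 in Zn(-)F1 and 200 in Zn(-/-)F2; arrays of the same number had a mean r of -0.010 and others 0.0053, so the numbers did not pair the arrays. With the sign turned for arrays with the sample in Cy3 they were 1 in Zn(+)F1, 7 in Zn(-)F1, 126 in Zn(+)F2, 143 in Zn(+/-)F2, 519 between Zn(+)F2 and Zn(+/-)F2, 1 for CtrlF1 against CtrlF0, 208 for CtrlF2 against CtrlF0, 169 for F1 minus F0 and 63 for F2 minus F0. The same turn reversed, in Zn(+)F1, vtg Rep_ASP1 F6 to -0.42, vtg precursor Rep_ASP1 H2 to -0.42, Mta_oud to -0.38, ad nucl translocase to -0.053 and acyl coa reductase to -0.189. In Zn(-)F1 it reversed chromobox to -0.036, Rep_ASP1 F6 to -0.109, Rep_ASP1 H2 to -0.06 and cyplasin s Rep_ASP8 A4 to -0.015. Between Zn(+)F1 and Zn(-)F1 it reversed Mta_oud to -0.43, Rep_ASP8 A4 to 0.35, Rep_ASP1 H2 to -0.36, Rep_ASP1 F6 to -0.317, rib 40S to -0.377, ad nucl translocase to -0.188 and ferritine_bis to -0.278. It did so in Zn(+)F2 with cyplasin s Rep_ASP8 A5 to 1.54 and rib 40S to 0.53, and in Zn(+/-)F2 with acyl coa reductase to -1.15. In Zn(-/-)F2 it reversed Rep_ASP1 H2 to 0.25, Rep_ASP1 F6 to 0.10, the yolk and egg list (adjusted p = 0.439), az aminotransferase to -0.60, acyl coa reductase to -1.36, rib 16S Rep_ASP8 F4 to -0.61 and Rep_ASP1 B5 to -0.38, rib 40S to 0.135, ferritine_oud to 0.037 and Mtb_bis to -0.695. Between Zn(+)F2 and Zn(+/-)F2 it turned Rep_ASP8 A5 to 1.40, for CtrlF1 against CtrlF2 ferritine_oud to 0.189, and for F1 minus F0 Mta_oud to -0.46 and Rep_ASP1 F6 to -0.572. Against this turn, Cy3 and Cy5 arrays within CtrlF2, Zn(+/-)F2 and Zn(-/-)F2 correlated positively as deposited (r from 0.273 to 0.757). With CtrlF0 replicates 1 and 3 as 2 samples the counts were 265 in ZnF0, 85 for CtrlF1 against CtrlF0, 127 for CtrlF2 against CtrlF0 and 34 for F2 minus F0, as counting equal columns as separate arrays lowers the spread within CtrlF0, and Mta for F2 minus F0 was at -0.045. With values beyond 5 set to missing CtrlF1 against CtrlF0 gave 6. Without the 6 uncentred arrays the counts were 393 in ZnF0, 3 between Zn(+)F1 and Zn(-)F1 and 141 for CtrlF1 against CtrlF0, with ferritine_oud for F1 minus F0 at -0.338 and cyplasin s Rep_ASP8 B4 in Zn(+)F1 at -0.133. Without the Zn(+)F1 replicate 2 array the count between Zn(+)F1 and Zn(-)F1 was 0, with ferritine_bis at -0.085. Counted over all lists, 2 passed in each of 6 alternatives (no dye coefficient, compared arrays alone, centred and scaled, median-centred only, replicate block, estimated correlation) and 4 with fry, on 2 yolk probes alone. With the sign turned the yolk and egg list passed neither in Zn(-/-)F2, as above, nor between Zn(+)F2 and Zn(+/-)F2 (adjusted p = 0.854). The median rho between effects was -0.082 with centred and scaled arrays, -0.122 with complete probes, -0.177 with array weights, 0.023 with the sign turned and -0.092 with values beyond 5 set to missing. With each replicate left out in turn, a group left with 1 array being assumed to vary like the others, the counts ran from 9 to 119 in ZnF0, 36 to 294 in Zn(+)F1, 146 to 207 in Zn(-)F1, 0 to 4 between Zn(+)F1 and Zn(-)F1, 60 to 283 in Zn(+)F2, 6 to 64 in Zn(+/-)F2, 114 to 416 in Zn(-/-)F2, 6 to 260 between Zn(+)F2 and Zn(+/-)F2, 0 to 10 for CtrlF1 against CtrlF0, 1 to 56 for CtrlF2 against CtrlF0, 75 to 322 for CtrlF1 against CtrlF2, 113 to 324 for F1 minus F0 and 6 to 76 for F2 minus F0. Signs turned over for rib 16S Rep_ASP1 B5 in ZnF0, from -0.003 without the averaged CtrlF0 array to 1.182 without CtrlF0 replicate 2, and for ferritine_bis between Zn(+)F1 and Zn(-)F1, from -0.085 to 0.512 without Zn(+)F1 replicates 2 and 1. Mtb_bis ran from -0.026 without CtrlF2 replicate 2 to 0.879 without Zn(+)F2 replicate 3 in Zn(+)F2, and from -0.019 to 0.716 without CtrlF2 replicates 2 and 3 in Zn(-/-)F2. Mtb_oud for CtrlF1 against CtrlF0 ran from -0.04 without the averaged CtrlF0 array to 0.37 without CtrlF0 replicate 2. For F1 minus F0, ferritine_oud ran from -0.054 to 0.08 without ZnF0 replicates 1 and 2, and for F2 minus F0, Mta from -0.455 without CtrlF0 replicate 2 to 0.777 without the averaged CtrlF0 array. The deposited ratios held no signal over background, so what it limits is not given.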

Other observations

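All tests in this part were chosen after the results were seen. Rep is the tag that the vitellogenin and cyplasin s probes carry, with Ene and Mol the other tags, and the sources do not expand them. Of the 94 probes called between Zn(+)F2 and Zn(+/-)F2, 68 were Rep probes, 63 of them higher in Zn(+)F2, which was 9.43% of tested Rep probes against 1.72% of the others (Fisher's exact adjusted p = 1.9e-14; probes are not independent replicates). In Zn(-/-)F2 against CtrlF2, Rep gave 97 of 224 calls, 75 of them lower (13.4% against 8.34%, Fisher's exact adjusted p = 0.0025). In Zn(+)F1 against CtrlF1, Rep gave 138 of 306 calls, 135 of them higher (20.1% against 11.3%, Fisher's exact adjusted p = 1.8e-06), and after centring the difference did not pass (adjusted p = 0.18). After centring Rep probes were called less often than the others in Zn(-)F1 against CtrlF1 (6.74% against 12.2%, Fisher's exact adjusted p = 5.6e-04), F1 minus F0 (12.6% against 18.9%, 0.0039) and CtrlF1 against CtrlF2 (14.6% against 19.4%, 0.022). As deposited none of these 3 passed (13.9% against 13.1%, 14.0% against 17.2% and 12.6% against 13.7%, with adjusted p = 0.87, 0.29 and 0.75). Mol probes were called more often after centring in Zn(-)F1 (13.6% against 8.84%, Fisher's exact adjusted p = 0.0039), in Zn(+)F2 (7.42% against 4.57%, 0.022) and for CtrlF1 against CtrlF2 (21.1% against 16.2%, 0.021), and less often in Zn(-/-)F2 (14.4% against 19.3%, 0.020) and between Zn(+)F2 and Zn(+/-)F2 (3.32% against 7.42%, 5.6e-04). As deposited only the last of these passed (2.12% against 5.26%, Fisher's exact adjusted p = 0.0025), the others having 0.635, 0.289, 0.289 and 0.0506 in that order. Ene probes were called less often as deposited in Zn(+)F1 (10.8% against 15.8%, Fisher's exact adjusted p = 0.0095, and 0.098 after centring). They were also called less often between Zn(+)F2 and Zn(+/-)F2 (1.34% against 5.65%, 3.6e-06, and 2.5e-05 after centring). Of the probes higher in Zn(+)F1 than in CtrlF1, 59 were also higher in Zn(+)F2 than in Zn(+/-)F2, against 10.4 if independent and a mean of 12.7 (highest 19) in 50 draws of simulated unchanged groups, and 39 against 5.39 if independent after centring. For Zn(-)F1 this overlap was 22 (simulated mean 11.3, highest 18), and 7 against 4.81 if independent after centring. For ZnF0 it was 1 (simulated mean 1.76, highest 5), and 13 against 2.59 if independent after centring. And 71 probes called in Zn(+)F1 and in Zn(-/-)F2 went in opposite directions, against 15.5 if independent and a simulated mean of 17.8 (highest 30), and 62 against 19.0 after centring. The dye coefficient enters the Zn(+)F1 change and cancels in both F2 changes where no value is missing.

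The r of Zn(+/-)F2 with Zn(-/-)F2 arrays ran from 0.121 to 0.798 over 9 pairs, against 0.344 to 0.461 within Zn(+/-)F2. Above that range were 2 pairs of the same dye (0.798 and 0.597) and 2 of opposite dye (0.526 and 0.477), while pairs of the same dye at 0.367 and 0.346 were not. Zn(+)F2 replicate 3 held the lowest value of the table, -45.1.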
